A study of Mus musculus with 16 samples.

How the data were processed

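Gene expression was measured in non-tumour colon taken at day 28 from 16 ApcMin/+ mice, which carry an inactivating mutation in 1 copy of the tumour suppressor Apc. Per the labels, 4 Sham mice drank water alone, 6 Control mice received dextran sulphate sodium (DSS, 1.5% by weight and volume) over 3 days, and saline, and 6 5-ASA mice received the same DSS course and 5-aminosalicylic acid (5-ASA). The labels differ on the dosing. Their protocol places 5-ASA or saline in the colorectum for 28 days, and their sample descriptions have 5-ASA, or plain water for Control, in the drinking water for 25 days after DSS. Cy3-labelled cRNA was made from 0.2 ug RNA and hybridised to 1-colour Agilent arrays, 1 per mouse, per the labels.

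The scanner files hold spot intensity, background-subtracted and detrended by Agilent Feature Extraction 10.10.1.1 and not normalised between arrays, per the file headers. The mean spot intensity and the median intensity around the spot are pixel values without correction, per the file headers. The other columns used are flags of 0 or 1 for signal well above background, saturation and outlying spots, per the file headers. Each array has 62976 spots in 384 spot rows and 164 columns, of which 59305 are not controls, and probe positions are those of mm9. The deposited value table holds 55821 probes and states no scale. Set against the scanner values, the authors' table matched log2 intensity shifted by each array's 75th percentile and centred per probe on the median of the 4 Sham arrays, with r from 0.979 to 0.991 and an interquartile range of the difference of 0.000199 per array. The highest absolute Sham median of any probe was 5e-07. The column medians were -0.000851, -0.0461, 0.0709 and -0.00654 for Sham 1 to 4. They were -0.0323, -0.0616, 0.206, -0.188, -0.0434 and 0.147 for Control 1 to 6, and 0.224, 0.178, 0.135, 0.136, 0.113 and 0.111 for 5-ASA 1 to 6. Scale, centring and direction were thus inferred from the values and not stated by the authors.

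From the scanner files, log2 of the processed intensity minus each array's 75th percentile was computed over the non-control probes, without outlying spots and with the spots of a probe averaged. Values are therefore log2 relative to the array's 75th percentile. Of 55681 probes, 27650 were named through the RefSeq gene table of assembly GRCm38.p6 by accession, 28031 kept the name in the files, and 1710 symbols were updated. The table was used for names alone. Probes well above background on at least 4 of 16 arrays were kept (35087), and each gene was represented by its kept probe with the highest mean, which left 24543 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), in 1 model of the 3 groups without covariates, and genes were called at a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. Where a gene was not well above background on any array of a group, the ratio is given as "at least N-fold". It sets the brighter group's mean against, per dim array, the higher of its lowest signal among probes well above background and the dim probe's own.

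Gene lists for the tissue and the treatment were fixed before the data were examined, as were the tests, most alternative settings and the rule for named genes. They comprise 34 lists with 561 genes, of which 33 had enough measured members to test (at least 4). Neutrophil, neutrophil-recruiting cytokines, and epithelial antimicrobial and acute phase were the 3 lists of first interest. Each list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, and adjusted over the lists of a comparison. A list score per mouse is the mean over members of the log2 value minus its mean over all arrays, compared by exact two-sided permutation. The smallest p this allows is 0.00476 for 4 against 6 mice and 0.00216 for 6 against 6. Correlations over the 12 DSS mice used 1e+05 permutations, and those over 6 mice used exact ones.

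Genes named per comparison were the 5 called with the highest and the 5 with the lowest difference among those whose groups did not overlap, or the 10 with the smallest p where fewer than 10 passed. To these were added the 3 members of each list of first interest with the smallest p, 2 members of each other list past the camera test until 30 genes were named, and S100a8, S100a9, Mpo, Cxcl2, Il1b, Lcn2, Apc, Pparg and Ptgs2. Transcripts without a gene name were passed over in the first step, and a few genes that the rule names are not reported here. Where 2 comparisons share a group, the correlation of their differences was taken with that group split in equal parts and set beside 50 simulations of unchanged groups.

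The alternative settings fixed at that time covered background correction (normexp with an offset of 50), quantile or median scaling, the filter on dim probes, and slide as a block, within each slide, or the array's position on the slide. They also covered the replicate number as a block, the samples in the model, trend and robust variance, array weights, the choice of probes per gene, the authors' table and leaving out each array. Runs without the outer 12 spot rows at each end of the array, runs with arrays of 1 position alone, and correlations of differences taken within a position were chosen after seeing the data. The model was tested on simulated data of 24473 genes with 100 genes changed per fold size. It recovered 65% of 2-fold and 93% of 4-fold changes for Control against Sham, 81% and 89% for 5-ASA against Control, and 73% and 96% for 5-ASA against Sham. Of 170, 182 and 180 calls, 12, 12 and 11 were false. The simulated errors were independent between genes and held no effect of array or spot position, so these rates need not hold for the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.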

Results

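Expression was measured in non-tumour colon of 16 ApcMin/+ mice at day 28, in 4 Sham, 6 Control and 6 5-ASA mice, with 1 array per mouse. DSS injures the colonic epithelium and causes colitis, and 5-ASA is an anti-inflammatory drug used in ulcerative colitis. The series title asks about 5-ASA, neutrophil activation and tumour burden, and the arrays address the state of the tissue around the tumours. Apc, the gene mutated in all groups, was at -2.04 ± 0.19 (SD, n = 4) in Sham, -2.11 ± 0.20 (n = 6) in Control and -2.16 ± 0.10 (n = 6) in 5-ASA, in log2 relative to the array's 75th percentile. Its probe does not check the mutation. The number of mice limits the precision: the median SE of a log2 difference was 0.16 for Control against Sham, 0.14 for 5-ASA against Control and 0.16 for 5-ASA against Sham. The arrays lay on 2 slides, each with 2 Sham, 3 Control and 3 5-ASA arrays. Within both slides, the first row of arrays held all Sham mice and Control 1, 2, 4 and 5, and the second row held all 5-ASA mice and Control 3 and 6. Sham and 5-ASA therefore shared no row. In the first row of both slides, Sham arrays lay in columns 1 and 2 of the slide and Control arrays in columns 3 and 4. Within that row, Control against Sham cannot be told apart from the column, and the row as a covariate does not remove it. Spots well above background made up 59.8% to 65.2% per array in the first row and 53.0% to 57.7% in the second, and the additive error was 4.05 to 5.72 against 8.12 to 11.2 intensity units. No array had a saturated spot (0), and arrays correlated with r from 0.958 to 0.993.

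The first comparison asked what a DSS course followed by saline left in the colon at day 28, against water alone. All 27 measured genes of the proliferation list, which holds replication and mitosis factors, were higher in Control, with a median difference of 0.72 on the log2 scale, and the list rose by camera (adjusted p = 3.51e-14). This call and every other list call between Control and Sham given here was lost with adjusted p = 0.794 with an estimated correlation. The list of neutrophil-recruiting cytokines rose as well, with 10 of 12 members higher and a median of 0.81 (camera adjusted p = 0.00788). The list epithelial antimicrobial and acute phase, which holds secreted defence proteins, rose with 13 of 17 members higher, a median of 0.48 and a mean of 0.89 (camera adjusted p = 0.00997). All 15 measured B cell markers were lower, with a median of -1.10 (camera adjusted p = 0.00527), or -2.09 without Sham 1 and, no longer called, -0.39 without Sham 2 and -0.52 without Control 1. The neutrophil list did not pass, with 12 of 23 members higher, a median of 0.003 and a mean of 0.28 (camera adjusted p = 0.448).

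Within these lists, few single genes passed. Mcm2 and Mcm4, subunits of the replicative helicase, were higher by 0.63 (SE 0.22) and 0.64 (SE 0.23), and for each the 6 Control mice did not overlap the 4 Sham mice. Neither passed over all genes in limma (adjusted p = 0.559). Among the antimicrobial genes, the acute phase protein Saa3 was higher by 2.78 (SE 0.70) without overlap, and the protease inhibitor Slpi by 1.87 (SE 0.60). Duoxa2, the maturation factor of an epithelial oxidase, differed by 0.83 (SE 0.35). Of that list 0 members passed over all genes and 1, Saa3, did when adjusted over the list alone. Of the cytokines 1, Ppbp, passed both ways, while Ccl3 (at least 1.59-fold) and Ccl4 (0.71, SE 0.38) did not. The members of the neutrophil list with the smallest p were Fpr1 (1.05, SE 0.36), Cd177 (0.98, SE 0.38) and S100a8 (1.75, SE 1.08). Cd177 was at 2.73 in Control and 1.76 in Sham, against -1.59 and -3.34 for S100a8, and whether it came from neutrophils was not tested. The alarmin S100a9 differed by 1.28 (SE 1.03), Il1b by 0.98 (SE 0.68), Lcn2 by 0.48 (SE 0.37), Mpo by -0.27 (SE 0.31), Pparg by 0.26 (SE 0.19), Ptgs2 by 0.13 (SE 0.33) and Apc by -0.07 (SE 0.11). Their adjusted p in limma ran from 0.559 to 0.932. In a model with the row as a covariate S100a8 was at 1.06, S100a9 at 0.65, Il1b at 0.59, Lcn2 at 0.09, Ptgs2 at 0.26 and Apc at -0.02, and 0 of them passed. Single mice moved several of these values. S100a9 was at 0.80 without Sham 1, 2.08 without Sham 2, 0.67 without Control 4 and 0.80 without Control 6, S100a8 at 1.14 without Control 4 and Lcn2 at 0.26 without Control 6. Il1b was at 0.49 without Sham 1, 0.61 without Control 4 and 0.64 without Control 6, Mpo at -0.09 without Sham 2, -0.41 without Control 1 and -0.13 without Control 4, and Pparg at 0.44, 0.17 and 0.09 without Sham 1, 2 and 3. Leaving out 1 mouse at a time, Apc ranged from -0.16 to -0.03 and Ptgs2 from -0.05 to 0.28. Cxcl2 was well above background on 1 array, that of Control 4, and was not tested.

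Other lists moved between Control and Sham by camera, each again with adjusted p = 0.794 with an estimated correlation. The erythroid list rose (5 of 5 higher, median 0.95, adjusted p = 0.00827) and so did the list matrix protease and plasminogen (9 of 11 higher, median 0.33, adjusted p = 0.0175). The reference list of housekeeping genes rose by a median of 0.10 (10 of 13 higher, adjusted p = 0.0444). Lower lists were fibroblast and matrix (17 of 22 lower, median -0.25, adjusted p = 0.00243), type I interferon (17 of 20, -0.31, adjusted p = 0.00347), smooth muscle (15 of 16, -0.31, adjusted p = 0.00827), enteric neuron and glia (13 of 16, -0.33, adjusted p = 0.0294) and circadian clock (11 of 15, -0.34, adjusted p = 0.0424). Examples were Fap at -0.43 (SE 0.18) and the matrix protein Lum at -0.59 (SE 0.26, or -0.36 with the array's row as a covariate). The viral RNA sensors Ifih1 and Ddx58 differed by -0.33 (SE 0.10) and -0.24 (SE 0.13), and the B cell genes Fcer2a and Cd37 by -1.10 (SE 0.65) and -0.79 (SE 0.51). Fcer2a was at -1.94 without Sham 1 and -0.60 without Sham 2, Cd37 at -1.25 without Sham 1, -0.46 without Sham 2 and -1.22 without Control 4, and Fap at -0.27 without Control 4. In all, 12 of 33 lists passed by camera, 6 higher and 6 lower. With an estimated correlation 0 passed, and each of the 12 had adjusted p = 0.794 with an estimated correlation. By fry 0 passed (smallest adjusted p = 0.552), and the exact two-sided permutation of list scores gave p = 0.00952 for proliferation (adjusted p = 0.314) and above 0.05 for the rest. On slides 1 and 2 the median was 0.55 and 0.90 for proliferation, 0.61 and 0.70 for neutrophil-recruiting cytokines, 0.53 and 0.61 for epithelial antimicrobial and acute phase, -0.95 and -1.14 for B cell, and 0.75 and 1.18 for erythroid. It was 0.26 and 0.57 for matrix protease and plasminogen, -0.19 and -0.22 for fibroblast and matrix, -0.50 and -0.00 for type I interferon, -0.08 and -0.53 for smooth muscle, -0.14 and -0.51 for enteric neuron and glia, -0.12 and -0.31 for circadian clock, and 0.11 and 0.04 for reference. For the neutrophil list, which did not pass, it was -0.001 and 0.48. With slide as a block each median was the same to 2 decimals, which the equal number of arrays of each group per slide fixes in advance. In that model circadian clock and reference no longer passed. With the array's row on the slide as a covariate, 6 of the 12 no longer passed: the cytokine list (0.43), the antimicrobial list (0.20), smooth muscle (-0.14), matrix protease and plasminogen (0.23), enteric neuron and glia (-0.21) and reference (0.09), the last also without the outer 12 spot rows (0.12). Aryl hydrocarbon and NRF2 target (0.16) and tuft cell (-0.25), not called without that covariate in the same model, were called with it. Leaving out Sham 1 left 6 lists called and ended 8 calls: circadian clock (-0.44), enteric neuron and glia (-0.07), epithelial antimicrobial and acute phase (0.48), fibroblast and matrix (-0.18), neutrophil-recruiting cytokines (0.50), reference (0.10), smooth muscle (-0.10) and type I interferon (-0.05). Without Control 4, calls ended for enteric neuron and glia (-0.08), the antimicrobial list (0.39), matrix protease and plasminogen (0.31), the cytokines (0.47), reference (0.08) and smooth muscle (-0.18). Without Control 6 they ended for circadian clock (-0.30), enteric neuron and glia (-0.18), matrix protease and plasminogen (0.28), reference (0.10) and smooth muscle (-0.14). B cell was not called without Sham 2 (-0.39) or Control 1 (-0.52), and stayed called at -2.09 without Sham 1 and -0.64 without Sham 4. Calls held with a moved median for enteric neuron and glia without Sham 3 (-0.56) or Control 1 (-0.51), smooth muscle without Control 1 (-0.50) and the antimicrobial list without Control 6 (0.30). Without Control 1 the erythroid call ended (0.47). Circadian clock was not called without Sham 2 (-0.15), Sham 3 (-0.25), Control 2 (-0.23) or Control 5 (-0.23), nor enteric neuron and glia without Sham 2 (-0.35). Reference was not called without Sham 2 (0.07), Sham 4 (0.08), Control 5 (0.10) or 5-ASA 2, 4 or 5 (0.10 each). The median, mean and test differed in sign for plasma cell (-0.06, 0.001, lower), interferon gamma and antigen presentation (-0.01, 0.13, higher), endothelial (0.02, -0.01, lower) and eicosanoid (0.01, 0.02, lower), none of which passed.

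**Figure D1:**
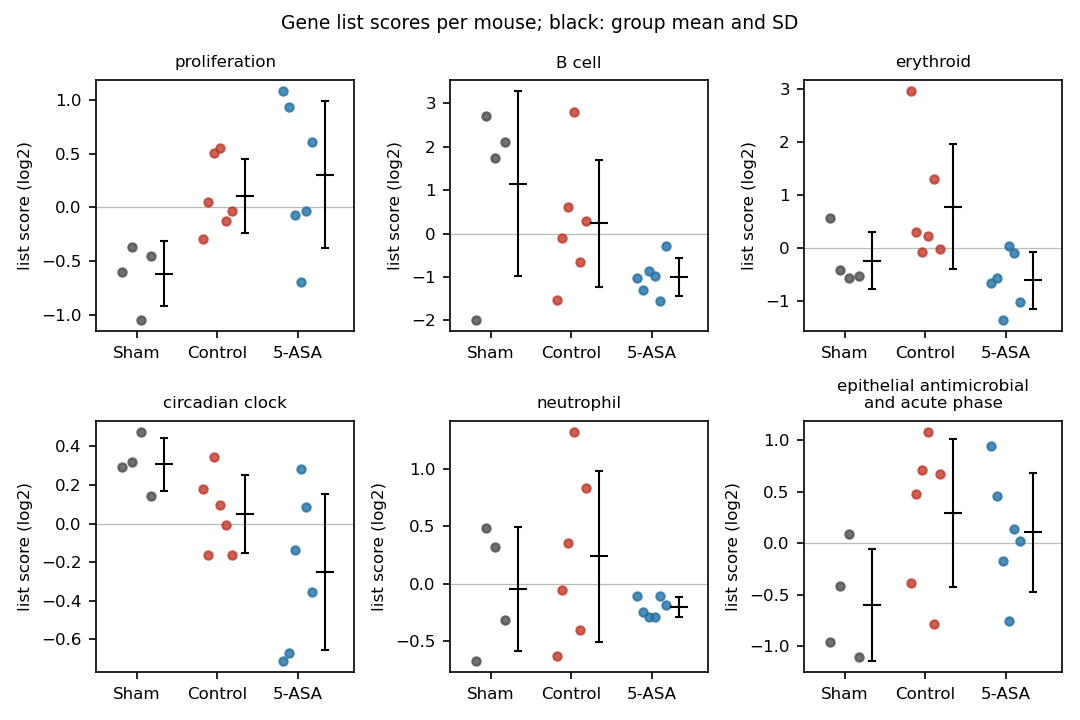
List scores per mouse in log2 for 6 gene lists, with 1 point per mouse in Sham (n = 4), Control (n = 6) and 5-ASA (n = 6) and the group mean and SD in black. Proliferation scores averaged -0.62 in Sham, 0.11 in Control and 0.30 in 5-ASA, and neutrophil scores spread from -0.63 to 1.32 in Control and from -0.29 to -0.11 in 5-ASA.

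Over all genes, limma called 14 genes between Control and Sham, 1 higher and 13 lower, all by at least 2-fold, and 2179 (8.88%) had an unadjusted p under 0.05, 1385 of them higher. The gene that rose was Ppbp, a platelet chemokine that attracts neutrophils. Ppbp was at -3.80 ± 0.80 (SD, n = 6) in Control and -6.20 ± 0.42 (n = 4) in Sham, a fitted difference of 2.40 (SE 0.37, adjusted p = 0.0242). Its probe lies on chromosome 5 from 91198970 to 91199029 (mm9) and was well above background on 5 of 6 Control and 0 of 4 Sham arrays, so that Ppbp was at least 2.81-fold higher. The difference in Ppbp was 2.28 on slide 1 and 2.51 on slide 2. With slide as a block it was 2.40 with adjusted p = 0.0422, in a range from 0.00728 to 0.972 over 36 alternatives, 17 of which kept the call. The Ppbp call ended with the row as a covariate (2.52, adjusted p = 0.0645), and without Sham 2 (2.37), Sham 3 (2.23), Sham 4 (2.41), Control 3 (2.39), Control 4 (2.40) or Control 5 (2.36). The 13 lower genes included Wdr72 at -4.93 (SE 0.34, adjusted p = 5.25e-06, at least 7.45-fold), the lens crystallin Crygc at -4.17 (SE 0.65, adjusted p = 0.0281), Speer4b at -3.22 (SE 0.45), the asparaginase family member Asrgl1 at -2.93 (SE 0.41) and the transporter family member Slc16a4 at -2.69 (SE 0.33). On slides 1 and 2 these were -5.33 and -4.53, -3.80 and -3.99, -2.67 and -3.77, -2.87 and -3.00, and -2.70 and -2.69. Crygc rests on 3 Sham mice, since its spot on the array of Sham 3 was left out as outlying, and its value on slide 2 rests on 1 Sham mouse. With the row as a covariate its call ended (-4.13, adjusted p = 0.131), and it was not called without Sham 1 (-3.94), Sham 2 (-3.85), Control 1 (-4.25), Control 3 (-4.22), Control 5 (-4.10), Control 6 (-4.09) or any of 5-ASA 1, 2, 5 or 6 (-4.17 each), nor Speer4b without Sham 2 (-3.11). All 13 lower genes have their probe in the last 8 of 384 spot rows, from row 377 on, where the outer 12 rows at both ends hold 6.85% of the genes tested. In those last 8 rows Sham exceeded the DSS groups by over 1.5 in 10.2% of probes, against 0.185% elsewhere. Without the outer 12 rows, 23294 genes remained and limma called 0, with 2074 at an unadjusted p under 0.05, and Ppbp then had adjusted p = 0.261 at the same difference of 2.40, its probe lying in spot row 294.

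**Figure D2:**
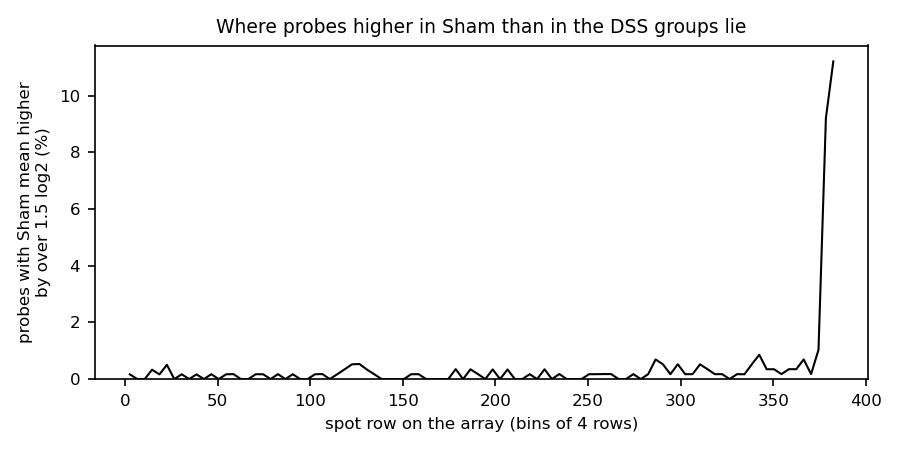
Share of probes (%) whose Sham mean (n = 4) exceeded the mean of the 12 DSS arrays by over 1.5 on the log2 scale, against spot row in bins of 4 rows. The share was 10.2% in the last 8 of 384 rows and 0.185% elsewhere.

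The comparison of 5-ASA with Control asked how the colon of DSS-treated mice differed with the drug. Stromal lists rose with 5-ASA by camera: fibroblast and matrix, with 19 of 22 members higher and a median of 0.29 (adjusted p = 7.6e-08), smooth muscle, with 15 of 16 and 0.40 (adjusted p = 5.59e-06), and enteric neuron and glia, with 16 of 16 and 0.32 (adjusted p = 0.00121). These calls were lost with adjusted p = 0.472, 0.614 and 0.628 with an estimated correlation. Blood and immune lists fell by camera. All 5 erythroid genes were lower, with a median of -1.49 (adjusted p = 3.8e-06), and all 15 B cell markers, with -1.05 (adjusted p = 3.8e-06). All 6 genes of the phagocyte NADPH oxidase were lower, with -0.54 (adjusted p = 0.0128). For these lists it was adjusted p = 0.472, 0.614 and 0.619 with an estimated correlation. Against Sham the oxidase list was also lower in 5-ASA (median -0.85) while the neutrophil list was at -0.01, so the oxidase list need not follow neutrophils. The neutrophil list fell, with 16 of 23 members lower and a median of -0.55 (adjusted p = 0.0235), as did neutrophil-recruiting cytokines, with 11 of 12 and -0.34 (adjusted p = 0.00546), and epithelial antimicrobial and acute phase, with 13 of 17 and -0.26 (adjusted p = 0.0235). None of these 3 held either, with adjusted p = 0.614, 0.603 and 0.619 with an estimated correlation. The neutrophil score averaged -0.20 ± 0.08 (SD, n = 6) in 5-ASA and 0.24 ± 0.75 (n = 6) in Control, where it was highest in Control 4 (1.32) and Control 6 (0.83). In the other Control mice it lay between -0.63 and 0.36, on both sides of the 5-ASA values. Control 4 and Control 6 also had the lowest Control scores for smooth muscle (-0.93 and -1.08) and for enteric neuron and glia (-1.20 and -0.86). Proliferation rose, with 22 of 27 members higher and a median of 0.29 (adjusted p = 0.00784, but adjusted p = 0.770 with an estimated correlation).

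Smaller shifts were seen in 4 more lists that fell by camera. These were absorptive colonocyte (17 of 21 lower, median -0.14, adjusted p = 0.00324), PPAR target (15 of 17, -0.08, adjusted p = 0.00549), circadian clock (12 of 15, -0.23, adjusted p = 0.0172) and monocyte and macrophage (18 of 20, -0.17, adjusted p = 0.0288). In that order they had adjusted p = 0.472, 0.472, 0.614 and 0.770 with an estimated correlation. In all 14 of 33 lists passed, 4 higher and 10 lower. With an estimated correlation 0 passed. By fry 0 passed (smallest adjusted p = 0.524). The exact two-sided permutation of list scores gave p = 0.00866 for erythroid (adjusted p = 0.286), 0.0498 for B cell and 0.197 for neutrophil. On slides 1 and 2 the median was -0.20 and -0.83 for neutrophil, -0.32 and -0.55 for neutrophil-recruiting cytokines, -0.04 and -0.40 for epithelial antimicrobial and acute phase, 0.11 and 0.37 for fibroblast and matrix, -2.01 and -0.99 for erythroid, -0.48 and -1.77 for B cell, and -0.11 and -0.86 for phagocyte NADPH oxidase. It was -0.06 and -0.12 for absorptive colonocyte and -0.13 and -0.07 for PPAR target. The direction differed between slides for smooth muscle (-0.13, 0.93), enteric neuron and glia (-0.19, 0.88), monocyte and macrophage (0.06, -0.39), proliferation (0.69, -0.14) and circadian clock (-0.59, 0.05). With slide as a block each median was the same to 2 decimals, as the equal group numbers per slide fix in advance, and all 14 lists passed. With the array's row as a covariate the median was -0.64 for neutrophil, -0.93 for the cytokines and 0.46 for fibroblast and matrix, and calls ended for erythroid (-0.76), absorptive colonocyte (-0.15), proliferation (0.08), circadian clock (-0.28) and monocyte and macrophage (-0.15), the last also without the outer 12 spot rows (-0.19). With that covariate the differences rest on the second-row arrays, where Control 3 and Control 6 are the only Control mice. Type I interferon, not called in the model without that covariate, was called with it (-0.32). Leaving out Control 4 ended the calls of neutrophil (-0.31), neutrophil-recruiting cytokines (-0.15), epithelial antimicrobial and acute phase (-0.10), phagocyte NADPH oxidase (-0.20), enteric neuron and glia (0.12) and monocyte and macrophage (-0.00). Leaving out Control 6 ended the same calls, at -0.35, -0.21, -0.22, -0.46, 0.15 and -0.12. The neutrophil call also ended without 5-ASA 1 (-0.46) or 5-ASA 4 (-0.39), the antimicrobial call without 5-ASA 3 (-0.25) or 5-ASA 4 (-0.24), and the oxidase call without 5-ASA 1 (-0.47). Monocyte and macrophage was not called without 5-ASA 1 (-0.06), 5-ASA 2 (-0.17) or 5-ASA 5 (-0.12), nor circadian clock without Control 1 (-0.18), 5-ASA 1 (-0.14) or 5-ASA 2 (-0.14). Proliferation was not called without Control 1 (0.18), Control 5 (0.23), 5-ASA 1 (0.11), 5-ASA 2 (0.13) or 5-ASA 6 (0.20), and stayed called at 0.52 without 5-ASA 4. Other calls held with a moved median. Without Control 4 it was -0.48 for B cell and 0.18 for fibroblast and matrix, and without Control 1 it was 0.60 for smooth muscle and 0.54 for enteric neuron and glia. Without Control 5 it was -0.55 for the cytokines and -0.47 for the antimicrobial list, and without Control 6 it was 0.20 for smooth muscle and -0.37 for circadian clock, which was at -0.14 without Control 3. Without 5-ASA 1 it was -0.39 for the antimicrobial list and -0.14 for PPAR target (-0.12 without 5-ASA 3). The neutrophil list was at -0.33 without 5-ASA 3 and -0.36 without 5-ASA 5, and monocyte and macrophage at -0.26 without 5-ASA 6. The median, mean and test differed in sign for enteroendocrine cell (0.003, -0.03, lower), intestinal stem cell and Wnt target (0.01, -0.02, higher) and eicosanoid (0.01, -0.01, higher), none of which passed.

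**Figure D3:**
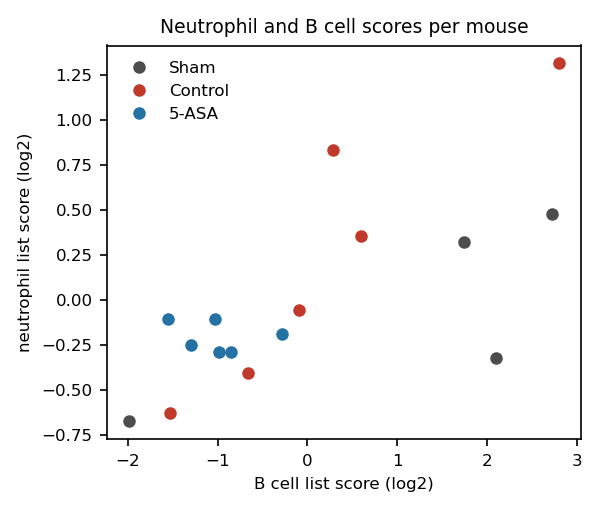
Neutrophil list score against B cell list score, both in log2, with 1 point per mouse coloured by group. Over the 6 Control mice the scores rose together (r = 0.922, exact two-sided p = 0.00278, rho = 0.943 with exact p = 0.0167, r = 0.806 without the 2 mice farthest from the median), while the 6 5-ASA mice lie between -0.29 and -0.11 on the neutrophil axis.

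No single gene passed between 5-ASA and Control: limma called 0 of 24543, with 993 (4.05%) at an unadjusted p under 0.05, 346 higher and 647 lower, and with the array's row as a covariate it called 7. The smallest adjusted p was that of Ppbp (0.359), which was at -5.90 ± 0.50 (SD, n = 6) in 5-ASA and not well above background on any of these arrays, so that it was at least 1.54-fold lower. Its fitted difference was -2.10 (SE 0.33), with -2.59 and -1.62 on slides 1 and 2. Slc26a6, an anion exchanger, differed by 0.52 (SE 0.12), Foxo6 by -0.66 (SE 0.17), the nucleotide receptor P2ry2 by -0.67 (SE 0.17), Gdap10 by -0.43 (SE 0.10) and the transporter family member Slc16a5 by -0.40 (SE 0.10), all without overlap and with adjusted p = 0.999 in limma. Treml1, a platelet receptor, differed by -0.70 (SE 0.18), and Col15a1, well above background on 1 5-ASA and 2 Control arrays, by 0.74 (SE 0.19). The odorant receptor genes Olfr1339 and Olfr1312, with fitted differences of -0.69 (SE 0.16) and -0.46 (SE 0.11), were well above background on 4 Control arrays and 0 5-ASA arrays, which bounds Olfr1312 at 1.09-fold lower or more and gives no bound for Olfr1339. In the neutrophil list the formyl peptide receptor Fpr1 differed by -0.80 (SE 0.32), the lectin Clec4d by -1.19 (SE 0.50) and haptoglobin, Hp, by -1.25 (SE 0.54), and 0 members passed over all genes or when adjusted over the list alone. Of the cytokines, Tnf differed by -0.84 (SE 0.56) and Cxcl1 by -0.79 (SE 0.67), and 1, Ppbp, passed when adjusted over the list alone. Complement C3 differed by -0.44 (SE 0.19), Duoxa2 by -0.64 (SE 0.31) and Lcn2 by -0.62 (SE 0.33). S100a8 and S100a9 differed by -1.30 (SE 0.96) and -1.28 (SE 0.92), Il1b by -0.44 (SE 0.61), Mpo by 0.55 (SE 0.28), Pparg by -0.36 (SE 0.17), Ptgs2 by -0.10 (SE 0.30) and Apc by -0.04 (SE 0.10). Of the lists other than these, Col5a2 and Fn1 differed by 0.49 (SE 0.13) and 0.35 (SE 0.12), and Bank1 by -1.43 (SE 0.75). Among these genes, moved with the row as a covariate were Tnf (-1.73), Cxcl1 (-2.04), C3 (-0.10), Duoxa2 (-1.06), Lcn2 (-1.41), S100a8 (-2.68), S100a9 (-2.53), Il1b (-1.21), Treml1 (-0.37) and Gdap10 (-0.64), while Apc (0.04) and Ptgs2 (0.17) turned, and 0 of them passed. These values rest on Control 3 and Control 6 as the only Control mice. Several values rest in part on Control 4 and Control 6. Without Control 4, S100a8 was at -0.69, S100a9 at -0.68, Bank1 at -0.84, Fpr1 at -0.51, Cxcl1 at -0.43 and Il1b at -0.07, and without Control 6, S100a9 was at -0.81, Cxcl1 at -0.46, Lcn2 at -0.40 and Il1b at -0.10. Il1b was also at -0.77 without Control 1, -0.68 without Control 5, -0.29 without 5-ASA 2 and -0.28 without 5-ASA 4. Leaving out 1 mouse at a time, Apc ranged from -0.08 to 0.005 and Ptgs2 from -0.33 to 0.07. When adjusted over the list alone, 4 of 5 erythroid genes fell: Slc4a1 (-1.97), Alas2 (-1.96), Hbb-b1 (-1.49) and Hba-a1 (-1.42), which were named after their values were seen. The probes of Tnf, Pparg and Slc26a6 lie in the first 12 spot rows, where Control 3 and 6 exceeded the other arrays by over 1.5 in 14.0% of probes, against 0.151% past row 200.

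The third comparison set 5-ASA mice against mice given water alone. All 27 proliferation genes were higher in 5-ASA, with a median of 0.99 (camera adjusted p = 7.5e-20), and 24 rose when adjusted over the list alone while 0 passed over all genes. The list calls of proliferation, B cell and circadian clock were each lost with adjusted p = 0.437 with an estimated correlation. Ube2c and the mitotic kinase Aurka were higher by 1.23 (SE 0.33, or 0.73 with the array's row as a covariate) and 1.30 (SE 0.36). All 15 B cell markers were lower, with a median of -1.97 (camera adjusted p = 5.41e-10, or adjusted p = 0.437 with an estimated correlation) and -3.19 without Sham 1. Of these Cd37 (-1.55, SE 0.51), Bank1 (-2.57, SE 0.84), Fcer2a (-1.96) and Cr2 (-3.27) fell when adjusted over the list alone. The circadian clock list fell, with 12 of 15 lower and a median of -0.54 (camera adjusted p = 3.51e-04, or adjusted p = 0.437 with an estimated correlation). The clock output genes Tef (-1.11, SE 0.31) and Dbp (-1.47, SE 0.46), with Per2 (-0.87) and Nr1d2 (-0.64), fell when adjusted over the list alone, whereas the activators Npas2 (0.50) and Arntl (0.36) were on the higher side. Mast cell markers rose, with 9 of 10 higher and a median of 1.12 (camera adjusted p = 0.0125, or adjusted p = 0.791 with an estimated correlation), 0 of them alone.

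Further lists that fell by camera in 5-ASA against Sham were type I interferon (19 of 20 lower, median -0.34, adjusted p = 7.51e-04), absorptive colonocyte (14 of 21, -0.25, adjusted p = 0.00447) and phagocyte NADPH oxidase (6 of 6, -0.85, adjusted p = 0.0216). In that order they had adjusted p = 0.817, 0.437 and 0.817 with an estimated correlation. Of absorptive colonocyte genes the sulphate transporter Slc26a2 fell when adjusted over the list alone (-0.77). In all 7 of 33 lists passed, 2 higher and 5 lower. The lists of first interest did not: the neutrophil median was -0.01 (adjusted p = 0.599), that of neutrophil-recruiting cytokines 0.39 (adjusted p = 0.599) and that of epithelial antimicrobial and acute phase 0.08 with a mean of 0.70 (adjusted p = 0.522), and 0 of their members passed over all genes or when adjusted over the list alone. With an estimated correlation 0 passed. By fry 0 passed (smallest adjusted p = 0.192). The exact two-sided permutation of list scores gave p = 0.0286 for circadian clock, 0.0429 for proliferation and for B cell and 0.0476 for mast cell, with adjusted p of 0.393 at the smallest. On slides 1 and 2 the median was 1.14 and 0.77 for proliferation, -1.43 and -2.87 for B cell, -0.86 and -0.44 for circadian clock, 0.88 and 1.18 for mast cell, -0.77 and -0.09 for type I interferon, -0.22 and -0.16 for absorptive colonocyte and -0.64 and -1.06 for phagocyte NADPH oxidase. It was -0.10 and -0.19 for neutrophil, 0.21 and 0.36 for neutrophil-recruiting cytokines and 0.26 and -0.12 for epithelial antimicrobial and acute phase. With slide as a block each median was the same to 2 decimals, again fixed by the equal group numbers per slide, and all 7 lists passed. Sham and 5-ASA shared no row of arrays, so the row can be set apart only through Control, and with the row as a covariate the median was 0.76 for proliferation, -2.42 for B cell and -0.70 for circadian clock, while mast cell (0.32) and absorptive colonocyte (-0.18) no longer passed. Called with that covariate, and not in the model without it, were neutrophil (-0.36), fibroblast and matrix (0.31), smooth muscle (0.64) and erythroid, which turned from -0.54 to 0.83. Leaving out Sham 1 ended the calls of absorptive colonocyte (-0.12), mast cell (1.18) and type I interferon (-0.14), and leaving out 5-ASA 5 that of mast cell (0.80). Without Sham 1 the median was -3.19 for B cell and -1.32 for phagocyte NADPH oxidase, both still called. Phagocyte NADPH oxidase was not called without Sham 2 (-0.60), Sham 3 (-0.72), Sham 4 (-0.74) or 5-ASA 4 (-0.86), and epithelial antimicrobial and acute phase passed without Sham 3 (0.27). The median, mean and test differed in sign for tuft cell (0.04, 0.06, lower) and stratified squamous epithelium (-0.04, 0.11, lower), neither of which passed.

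Over all genes limma called 14 between 5-ASA and Sham, 1 higher and 13 lower, 12 of them by at least 2-fold, with 2665 (10.9%) at an unadjusted p under 0.05, 1508 of them higher. Mcm8, a helicase of homologous recombination, rose by 0.84 (SE 0.12, adjusted p = 0.0121), from -2.81 ± 0.15 (SD, n = 4) in Sham to -1.97 ± 0.26 (n = 6), without overlap, with 0.78 and 0.89 on slides 1 and 2. With slide as a block Mcm8 had adjusted p = 0.00999, in a range from 0.00263 to 1 over 35 alternatives, and its call ended without Sham 3 (0.81) or Sham 4 (0.78). It also ended with the row as a covariate (0.84, adjusted p = 1.00) and without the outer spot rows (0.84, adjusted p = 0.123), in both cases with the difference unchanged to 2 decimals. Osgin1, an oxidative stress gene, fell by 0.54 (SE 0.09, adjusted p = 0.0326), and was named after its values were seen. The other 12 lower genes lie in the last 8 spot rows and were also lower in Control than in Sham: Crygc at -4.19 (SE 0.65, at least 6.07-fold), Wdr72 at -4.11 (SE 0.34, at least 4.23-fold), Asrgl1 at -3.66 (SE 0.41, at least 3.23-fold), Slc16a4 at -3.36 (SE 0.33, at least 3.60-fold) and Speer4b at -3.28 (SE 0.45, at least 3.90-fold) among them. Each was above background on 0 of 6 5-ASA arrays and on 4 of 4 Sham arrays, or on the 3 of 3 in use for Crygc. With the row as a covariate, of these 5 only Wdr72 stayed called (-5.24), while Crygc was at -4.07, Slc16a4 at -2.87, Asrgl1 at -2.77 and Speer4b at -1.94. On slides 1 and 2 these 5 were -4.49 and -3.34, -4.48 and -3.74, -3.76 and -3.56, -3.18 and -3.54, and -2.95 and -3.60, with 1 Sham mouse for Crygc on slide 2. Crygc was not called without Sham 1 (-3.96), Sham 2 (-3.87), Control 3 or 5 (-4.19 each), 5-ASA 1 (-4.17), 5-ASA 2 (-4.23), 5-ASA 3 (-4.33), 5-ASA 5 (-4.09) or 5-ASA 6 (-4.10). Without the outer 12 spot rows limma called 0 genes, with 2472 at an unadjusted p under 0.05, and without 5-ASA 4 it called 23. In the lists of first interest, Stfa2l1 (-0.87, SE 0.51), Mmp9 (-0.81, SE 0.52), Cxcl5 (2.05, SE 1.15), Ccl4 (0.48, SE 0.38), Pf4 (-0.26, SE 0.22), C3 (-0.65, SE 0.21), Saa3 (2.11, SE 0.70) and Tifa (0.85, SE 0.29, without overlap) were among those with the smallest p and did not pass. S100a8 differed by 0.45 (SE 1.08), S100a9 by -0.01 (SE 1.03), Mpo by 0.28 (SE 0.31), Il1b by 0.54 (SE 0.68), Lcn2 by -0.14 (SE 0.37), Pparg by -0.10 (SE 0.19), Apc by -0.11 (SE 0.11) and Ptgs2 by 0.02 (SE 0.33), the last turning to -0.001 with median scaling. The adjusted p of these genes in limma ran from 0.347 to 0.999. Under the row covariate Cxcl5 was at 0.25, C3 at -0.14, Pf4 at -0.02, Stfa2l1 at -1.56, Mmp9 at -1.54, S100a9 at -1.88, Lcn2 at -1.33, Mpo at 0.53, Pparg at -0.25 and Ptgs2 at 0.43, while Ccl4 (-0.18), S100a8 (-1.63), Il1b (-0.62) and Apc (0.02) turned, and 0 of them passed. Leaving out 1 mouse at a time, S100a8 ranged from 0.16 (without Sham 1) to 1.14 (without Sham 2), S100a9 from -0.48 to 0.80 (the same mice), Il1b from 0.05 to 0.87 (the same mice), Mpo from 0.15 (Sham 3) to 0.45 (Sham 2) and Lcn2 from -0.33 (5-ASA 5) to -0.04 (5-ASA 2). Pparg ranged from -0.27 (Sham 3) to 0.08 (Sham 1), Ptgs2 from -0.20 (5-ASA 5) to 0.17 (Sham 1) and Apc from -0.20 (Sham 4) to -0.07 (Sham 3). Pf4 was at -0.12 without Sham 3 and -0.09 without 5-ASA 1, Ccl4 at 0.28 without Sham 1 and Stfa2l1 at -0.47 without 5-ASA 6.

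Set side by side, the differences of Control and of 5-ASA from Sham correlated across genes, but on average not when each difference was taken within a row of arrays. Both DSS groups hold second-row arrays and Sham holds none, so a row effect can raise the correlation. With the 4 Sham arrays split 2 and 2 so that no array served both sides, the log2 differences of Control and 5-ASA against Sham correlated over 24473 genes with a mean r of 0.284 (0.155 to 0.435 over 6 splits) and a covariance of 0.0496. Genes are not independent replicates. Without the split r was 0.738 and the covariance 0.0977, against 0.599 and 0.0448 in simulations of unchanged groups with shared Sham arrays. With the 2 differences taken from opposite slides, each against the Sham arrays of its own slide, r was 0.391 and 0.446. Of the lower calls 12 were common to both comparisons, and all 12 lie in the outer spot rows. Independent lists of that size would share 0.00689, but both comparisons use the same Sham arrays. Simulations gave 0, but no gene was changed in them, so that value was nearly fixed in advance. Neither value speaks for a shared change after DSS. With each difference taken within a row, from first-row Control and Sham and from 5-ASA and second-row Control, the mean r was -0.0424 (-0.443 to 0.303 over 36 splits). That range holds the mean of 0.284 above and rests on fewer arrays, so it does not show that the row was the source. A return toward Sham under 5-ASA could not be told apart from the row of the arrays, which can move both differences in the same direction. With the Control arrays split 3 and 3, the differences Control against Sham and 5-ASA against Control had a mean r of 0.135 (-0.157 to 0.326 over 20 splits), where a return gives a negative value, and a covariance of 0.0195. It was 0.0827 with probes above background on all arrays, and with the 2 differences taken from opposite slides r was -0.042 and 0.098. Within rows, with no array on both sides, r was -0.137, from 2 second-row Control arrays. Without the split r was -0.182 with a covariance of -0.0166, and simulated unchanged groups gave -0.447 and -0.0299.

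The diarrhea score at day 28 was given per mouse. It was 0.833 ± 0.408 (SD, n = 6) in Control, 0.333 ± 0.258 (n = 6) in 5-ASA and 0.375 ± 0.25 (n = 4) in Sham. Exact two-sided permutation gave p = 0.124 for Control against Sham, p = 0.0758 for 5-ASA against Control and p = 1 for 5-ASA against Sham, or 0.186, 0.186 and 1 after adjustment over the 3. Over the 12 DSS mice the neutrophil score correlated with the diarrhea score at r = 0.596 (permutation p = 0.0465, two-sided, adjusted p = 0.270 over 12 relations) and rho = 0.446 (permutation p = 0.152). Without Control 3 and Control 4, the 2 mice farthest from the median score, r was 0.458. Within groups r was 0.630 in Control (n = 6, exact p = 0.2, rho = 0.741 with exact p = 0.133). In 5-ASA it was -0.904 (n = 6, exact p = 0.0667, rho = -0.828 with exact p = 0.133), so the direction differed between the groups. The 5-ASA mice scored only 0 or 0.5, and 0.0667 is the smallest exact p these scores allow. No relation within 5-ASA could therefore pass. Without the 2 mice farthest from the median score r was 0.930 in Control, and in 5-ASA the remaining scores were equal. Among the DSS mice of slide 1 r was 0.616 (n = 6, exact p = 0.233, rho = 0.338 with exact p = 0.667). On slide 2 it was 0.775 (n = 6, exact p = 0.1, rho = 0.555 with exact p = 0.267) and rested on Control 4 and Control 6, with -0.729 without them. For neutrophil-recruiting cytokines r was 0.543 over the 12 mice (permutation p = 0.0674, adjusted p = 0.270, rho = 0.411 with permutation p = 0.190), 0.302 without Control 3 and Control 4, and 0.701 and 0.624 on slides 1 and 2, the latter turning to -0.705 without Control 4 and Control 6. For epithelial antimicrobial and acute phase r was 0.292 (permutation p = 0.363, rho = 0.305 with permutation p = 0.340), turning to -0.113 without Control 3 and Control 4, and on the slides it was 0.053 and 0.551. For absorptive colonocyte r was 0.373 (permutation p = 0.236, rho = 0.411 with permutation p = 0.191) and 0.238 without them, and on the slides it was 0.648 and 0.170. No relation of the 12 passed after adjustment.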

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

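All tests reported in this part were chosen after the results they address were seen. In 11 of 224 groups of 4 or 6 mice, a single mouse lay farther from the others than the 95% critical value of Dixon's ratio allows, where chance gives about 1 in 20 groups, or 11.2. Sham 1 was that mouse 4 times. Among Sham mice, its score was -1.001 for neutrophil-recruiting cytokines against -0.28 to -0.18, 0.55 for erythroid against -0.57 to -0.42, and -0.88 for phagocyte NADPH oxidase against 0.60 to 0.90. Its diarrhea score was 0 against 0.5 in each of the others. Sham 2 was apart for Wdr72, at -1.09 against -2.85 to -2.64, and for S100a8, at -1.27 against -4.20 to -3.88. Sham 3 was apart for Fpr1, at -3.33 against -3.97 to -3.92. Control 6 had a mast cell score of 1.50 against -0.74 to 0.08, and Control 4 had Cd37 at 2.18 against -0.84 to -0.06. In 5-ASA, mouse 6 was apart for P2ry2, at 0.77 against 1.09 to 1.25, and mouse 4 for the platelet gene Treml1, at -3.70 against -4.34 to -4.27.

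The first pattern is the set of 12 genes called lower than Sham in both DSS groups, among them Wdr72, Crygc, Asrgl1, Slc16a4 and Speer4b. Of their probes 100% lie in the outer 12 spot rows, which hold 6.85% of the genes tested (Fisher's exact test, two-sided, p = 1.03e-14), so signal near the array edge is a candidate source. For 2 of the transcripts, 4 other probes were measured, and the median of Sham minus DSS over them was -0.16 (SD 0.15). In 1 transcript, on chromosome 5, these probes were well above background on all 4 Sham and 12 DSS arrays. Their differences of -0.06 and -0.03 argue against lower expression of that transcript in the DSS groups. Those of the other transcript were well above background on only 1 and 2 Sham arrays, and leave it open. For 6 transcripts, 13 other probes were well above background on at most 1 Sham array and decide nothing, and 4 transcripts have no other probe away from the edge. A lower expression after DSS stays open for all of these transcripts but the 1 on chromosome 5.

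The second pattern is the spread of neutrophil list scores among Control mice, with an SD of 0.746 over 6 mice against 0.08 in 5-ASA. The position of the array on the slide is left open, since the SD over the 4 first-row Control arrays was 0.872 and fell to 0.289 without Control 4. More immune cells of every kind in the tissue sampled may account for the spread: over the 6 Control mice the neutrophil score correlated with the B cell score at r = 0.922 (exact two-sided p = 0.00278, adjusted p = 0.00833 over 6 relations, rho = 0.943 with exact p = 0.0167), with the T and cytotoxic cell score at r = 0.900 (exact p = 0.00278, rho = 0.943) and with the monocyte and macrophage score at r = 0.940 (exact p = 0.00417, rho = 0.943). Without the 2 mice farthest from the median these were 0.806, 0.904 and 0.718. Over the 6 5-ASA mice r was -0.254, -0.289 and -0.561 (exact p = 0.639, 0.517 and 0.251). Without 2 mice left out by the same rule, the 5-ASA values moved to -0.154, 0.451 and -0.989. Severity by the diarrhea score, with r = 0.630 over the 6 Control mice (exact p = 0.2), cannot be told apart from chance at this number of mice.

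The third pattern is Ppbp, higher in Control than in Sham. Blood in the tissue sampled is a candidate source, since the erythroid list rose too and Control 1 had both the highest Ppbp (-2.47) and the highest Hba-a1 (7.88). With values not well above background, as on all Sham arrays, set at the lowest such signal of their array, the difference was 1.49 (SE 0.33), and 1.05 (SE 0.28) with the erythroid score as a covariate, so blood stays open as a source. Over first-row arrays alone it was 1.62 (SE 0.49) in the same way, and so no smaller than over all arrays. In that row Sham and Control arrays lay in different columns of the slide, so the position of the array on the slide stays open too. Of other platelet genes, chosen after their values were seen, Pf4 differed by -0.07 (SE 0.22), Gp1bb by 0.10 (SE 0.13), Clec1b by 0.18 (SE 0.18) and Treml1 by 0.48 (SE 0.20), and platelets or another source of Ppbp after DSS stay open.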

How the results depend on the processing

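Settings without the outer 12 spot rows, with arrays of 1 row of the slide alone, with differences taken within rows, and with 2 of these choices together were chosen after the data were seen, and the others in advance. The lists depend most on the test: camera with an estimated correlation called 0 lists in each comparison, and fry, which does not set a list against other genes, called 0 in each. Gene counts depend on dim spots and on position. Without a filter on dim probes limma called 2937 genes for 5-ASA against Control (2886 higher) and 3271 for 5-ASA against Sham (3137 higher). Background differed between the rows of arrays, and with the row as a covariate and no filter these counts were 42 and 30, all lower. With probes above background on all 16 arrays, 1 gene was called for Control against Sham and 2 for 5-ASA against Sham. With the row as a covariate 7 genes were called for 5-ASA against Control and 8 for 5-ASA against Sham, all lower. Without the outer 12 spot rows 0 were called for Control against Sham and 0 for 5-ASA against Sham, and with the row added 0, 1 (5-ASA against Control) and 0. Over first-row arrays alone 1 gene and 7 lists were called for Control against Sham, or 0 and 6 without the outer rows, and over second-row arrays without them 9 lists for 5-ASA against Control. On slide 1 alone, with fewer mice, 4 genes and 7 lists were called for Control against Sham, 8 lists for 5-ASA against Control, and 2 genes and 11 lists for 5-ASA against Sham. On slide 2 alone 1, 1 and 4 genes were called. A model of the 2 groups compared called 7 genes for Control against Sham, array weights 6 lists for that comparison, and all probes in place of 1 per gene 22 for 5-ASA against Sham. The cause of these last 3 was not tested. With the replicate number as a block, 10, 0 and 12 genes and 10, 14 and 7 lists were called. The diarrhea relation of epithelial antimicrobial and acute phase turned to -0.113 without Control 3 and Control 4. The correlation across genes for a return toward Sham turned to -0.137 within rows of arrays, to -0.836 over called genes, most of them near the array edge, and to -0.182 without splitting Control, where the shared arrays pull it down by construction. That for the shared change turned to -0.0424 within rows and rose to 0.856 and 0.738 in the other 2 settings.

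Among the genes and lists followed through all settings, directions turned as follows, and the cause was not tested. Lists that were neither called nor of first interest were not followed in this way, but were fitted with the row as a covariate. For 5-ASA against Sham it turned erythroid from -0.54 to 0.83, which passed. It also turned adipocyte from -0.67 to 0.0568, Paneth cell from 0.66 to -0.12, goblet cell from 0.19 to -0.11, tuft cell from 0.0361 to -0.20, monocyte and macrophage from 0.0388 to -0.13, enteroendocrine cell from -0.18 to 0.000878, intestinal stem cell and Wnt target from 0.0676 to -0.0207 and plasma cell from -0.0160 to 0.0462, none of which passed. For 5-ASA against Control it turned adipocyte from -0.51 to 0.0282, Paneth cell from 0.31 to -0.00984, tuft cell from 0.12 to -0.0468, goblet cell from 0.0330 to -0.12, intestinal stem cell and Wnt target from 0.00721 to -0.14 and enteroendocrine cell from 0.00347 to -0.0291. For Control against Sham it turned stratified squamous epithelium from 0.12 to -0.0329, intestinal stem cell and Wnt target from 0.0294 to -0.0399, goblet cell from 0.0629 to -0.0122 and interferon gamma and antigen presentation from -0.00884 to 0.0197, and none of these passed in either comparison. For Control against Sham, S100a9 was at -0.27, Apc at 0.0212 and the neutrophil list at -0.00101 on slide 1. Apc was at 0.00319 with the replicate block and 0.0579 with array weights. The neutrophil list was at -0.0447 with array weights, and at -0.0403 both on first-row arrays and with the row as a covariate. For 5-ASA against Control on slide 1, Il1b was at 0.26, smooth muscle at -0.13, enteric neuron and glia at -0.19 and monocyte and macrophage at 0.0574. On slide 2 Apc was at 0.0354, proliferation at -0.14 and circadian clock at 0.0528. With the row as a covariate, and on second-row arrays alone, with or without the outer spot rows, Apc was at 0.0432 and Ptgs2 at 0.17. With array weights Il1b was at 0.20, Ptgs2 at 0.0563 and monocyte and macrophage at 0.0418. For 5-ASA against Sham, Ptgs2 was at -0.00113 with median scaling and -0.0308 with the replicate block. On slide 1 S100a8 was at -0.20 and Mpo at -0.10, and on slide 2 S100a9 was at 1.06, Lcn2 at 0.26, Pparg at 0.0355 and epithelial antimicrobial and acute phase at -0.12. With the row as a covariate Ccl4 was at -0.18, S100a8 at -1.63, Il1b at -0.62 and Apc at 0.0188, with or without the filter or the outer spot rows. In that setting epithelial antimicrobial and acute phase was at -0.14 and neutrophil-recruiting cytokines at -0.47, or -0.24 and -0.35 without the outer spot rows. The direction of camera alone turned for epithelial antimicrobial and acute phase without a filter (median 0.13) and for neutrophil-recruiting cytokines with probes above background on all arrays (median 0.14).

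Leaving out 1 array at a time gave 10 to 16 called genes for Control against Sham, 0 to 0 for 5-ASA against Control, and 11 to 23 for 5-ASA against Sham. The lists called ranged from 6 (without Sham 1) to 13, from 10 to 16 and from 6 to 9. The difference in diarrhea score ranged from 0.325 to 0.525 for Control against Sham, from -0.567 to -0.367 for 5-ASA against Control, and from -0.167 to 0.025 for 5-ASA against Sham. Without 1 array the direction turned within these ranges, lowest to highest. Ptgs2 ranged from -0.0468 to 0.276 for Control against Sham, from -0.327 to 0.0700 for 5-ASA against Control and from -0.201 to 0.174 for 5-ASA against Sham. The neutrophil list ranged from -0.0233 to 0.400 for Control against Sham and from -0.0976 to 0.0702 for 5-ASA against Sham. For 5-ASA against Control Apc ranged from -0.0807 to 0.00493, and for 5-ASA against Sham S100a9 ranged from -0.483 to 0.798 and Pparg from -0.273 to 0.0822. Of the lists called, 65 of 216 values for Control against Sham, 55 of 252 for 5-ASA against Control and 26 of 126 for 5-ASA against Sham no longer passed under the settings chosen in advance other than leaving out 1 array. A further 6 turned for 5-ASA against Control, and the rest of these kept direction and call. Leaving out 1 array ended 33 of 192, 28 of 224 and 8 of 112 more. Array background limits dim genes such as Ppbp, which was well above background on 5 arrays.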

Other observations

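The tests of gene counts for 5-ASA against Control and of both counts without the outer spot rows were chosen after the results were seen. Other tests in this part were written down first. The B cell score varied widely between mice of a group. It was -1.99 in Sham 1 and 1.75 to 2.72 in the other Sham mice, 2.81 in Control 4, and -1.55 to -0.28 in the 6 5-ASA mice. The erythroid score was 2.95 in Control 1 and 1.31 in Control 5. The neutrophil attractants Cxcl2 and Cxcl3 and the cytokine Il17a were well above background on 1 array each, that of Control 4, at -4.77, -4.77 and -2.46. Il6 was so on 3 arrays, those of Control 4 (-4.25), 5-ASA 5 (-4.86) and 5-ASA 6 (-4.58). These 4 genes were not tested, and Cxcl3, Il17a and Il6 were chosen after their values were seen.

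Other splits of the same arrays into groups of the same sizes, 100 per comparison with the real one included, show how often chance gives as many calls. For Control against Sham 3 of 100 splits, the real one included, called at least the real 14 genes, so few splits gave as many. Of these 14 genes, 13 have their probe in the last 8 spot rows. The count therefore does not tell an effect of DSS from signal near the array edge. The highest other split called 831 genes, many times the real count, which points to a structure of the samples that the groups do not follow, with Sham 1 and 4 and Control 1, 2, 3 and 5 on one side. For 5-ASA against Sham it was 2 of 100 for the real 14, of which 12 have their probe in the last 8 spot rows, so the same limit holds. The highest other split there, with all Sham mice and 5-ASA 3 and 4 on one side, called 806, which points to a structure as well. For 5-ASA against Control the real count was 0 genes, which 100 of 100 splits reach whatever the data, so chance is left open, and the highest other called 65, with Control 1, 2 and 5 and 5-ASA 3, 4 and 5 on one side. Without the outer 12 spot rows the real count was 0 for Control against Sham and for 5-ASA against Sham, which 100 of 100 splits reach in each for the same reason, with 834 and 775 as the highest others, so these 2 counts decide nothing either. For the lists chance could not be excluded. At least the real 12 lists were called in 37 of 100 splits for Control against Sham (highest other 22), the real 14 in 29 of 100 for 5-ASA against Control (highest other 20), and the real 7 in 74 of 100 for 5-ASA against Sham (highest other 18). For the shared change of both DSS groups, 6 of 100 regroupings of the 16 arrays gave a covariance of at least the real 0.0496 (highest other 0.0835), so chance was not excluded.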
